A study of Solanum tuberosum with 5 samples.

How the data were processed

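Potato plantlets of the genotype labelled E26 were grown in long days (LD) for 3 weeks and then either kept in LD or moved to short days (SD). Plantlets were taken at the time of transfer (day 0, LD) and after 2 and 5 days in each photoperiod, which gave 5 groups with 1 library each: LD day 0, LD day 2, LD day 5, SD day 2 and SD day 5. Polyadenylated RNA was profiled as a tag library, in which each transcript is represented by a short sequence next to a restriction site, prepared with the Illumina Gene Expression Sample Prep Kit per the labels' protocols.

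Each deposited file lists 21-base tags with 1 value per tag. All tags start with CATG, the recognition site of the restriction enzyme NlaIII, and no tag was listed more than once in a library. The authors' column is headed TPM, per the file headers. The deposited values are tags per 1000000 tags of the library (a reads-per-total unit, RPM, given below as TPM after the authors' header), with no division by transcript length. This was read from the values themselves, since each library's values were whole multiples of 1 step within 0.006 TPM for at least 99.98% of the listed tags, with 2 exceptions in LD day 5 and 3 in SD day 2. The lowest value equalled 2 steps in every library. The aligner, the reference, the genome build and the filters on tags are not given in the sources used here. The step gave library totals of 3548031 tags for LD day 0, 3545582 for LD day 2, 3688118 for LD day 5, 3507407 for SD day 2 and 3492458 for SD day 5. The listed values summed to between 50.9% and 59.7% of these totals.

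The files pair no tag with a gene, and no potato sequence was in hand to match tags to transcripts. Tags are therefore reported by sequence, and the 31 gene lists that were fixed before the data were examined could not be evaluated. A tag missing from a library was treated as not compared, not as 0, because in the 8 pairs compared between 19.2% and 26.8% of the tags above 50 TPM in 1 library were not listed in the other, although 2 tags were enough to be listed. Each comparison used the tags listed in both of its libraries.

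For each tag the log2 ratio was computed from the deposited TPM values with a pseudocount of 1 TPM. A tag was called higher or lower when the log2 ratio was at least 1 in size, the value in the higher library was at least 10 TPM, and the exact 95% counting interval of the ratio excluded 1. The interval was the Clopper-Pearson interval of the recovered whole tags conditional on their sum, computed with scipy 1.17.1. A value of 10 TPM rests on 34.9 to 36.9 tags, depending on the library, and has a relative counting error of 32.3% to 33.2% at that confidence. Intervals cover counting error only, since tags without molecular identifiers are not independent molecules. With 1 library per group there is no replicate check, no p-value was computed for a pair of libraries, and a call describes 2 libraries, not 2 conditions. Fold values are ratios of the deposited values without the pseudocount.

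By a rule fixed before the data were examined, at most 2 tags higher and 2 lower were named per comparison, those with the largest log2 ratios. The same number was named among tags called the same way on both days, ranked by the mean of both log2 ratios. The most abundant tags and the tags called in opposite ways were chosen after their values were seen. Overlap between days was set beside the number expected of independent lists, the product of the 2 list sizes divided by the number of tags compared. The SD and LD pairs of day 2 and day 5 share no library.

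The calling procedure was tested on simulated data with counting error only. For SD against LD at day 2, 0% of the changed tags at 1.5-fold were called, 92% at 2.5-fold, and 100% at 4-fold and 8-fold, with 50 tags at each size, and 7 of 12044 unchanged tags were called. For day 5, 92% at 2.5-fold and 100% at 4-fold were called, with 6 of 12508 unchanged tags called. A limma fit on log2(value + 1) was added after the data had been seen, with day as a block over the 4 libraries of days 2 and 5, so that days stood in for replicates. In 20 simulated sets of the same 6381 tags, each with 200 tags changed 4-fold and the same log2 spread of 0.5 for every tag, that fit recovered 69% of the changed tags on average (41% to 83%), with 5.7 false calls on average and at most 17. The changed tags were drawn only from those with a mean log2(value + 1) above 5, and all were raised in SD. The recovered share therefore does not describe less abundant tags. The simulated spread was uniform, so these shares do not carry over to data in which the spread differs between tags.

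Alternatives were TMM and median-of-ratios scaling (both formulas computed in Python over the 8910 tags listed in all libraries), pseudocounts of 0.1 and 5 TPM, no floor and a floor of 50 TPM, the rule without the counting interval, and other LD libraries as the control. Alternatives added after the data had been seen were setting unlisted tags to 0, adding rows listed under different tags, rescaling to the listed tags, and using only tags listed in all 5 libraries. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, R 4.3.3 and limma 3.58.1.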

Results

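The series followed the transcriptome of potato plantlets as they were moved from long days (LD) to short days (SD), a photoperiod that favours tuber formation in potato. Plantlets of 5 groups were profiled, with 1 tag library each: LD day 0 before the transfer, LD day 2, LD day 5, SD day 2 and SD day 5. Library totals were similar, from 3492458 tags in SD day 5 to 3688118 in LD day 5. The files listed 17005 tags for LD day 0, 17260 for LD day 2, 17239 for LD day 5, 16637 for SD day 2 and 16734 for SD day 5. Of 27553 distinct tags, 8910 were listed in all 5 libraries. All values below are tags per 1000000 tags of the library (TPM), and since no group has replicates, the intervals given are 95% counting intervals of a ratio between 2 libraries.

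The most abundant tags differed between libraries by more than counting error. CATGGTTTTTTATGTTTGGTT had the highest mean value, with 3096 TPM in LD day 0, 10796 in LD day 2, 9349 in LD day 5, 1103 in SD day 2 and 9586 in SD day 5. It was 9.79-fold lower in SD day 2 than in LD day 2 (interval 9.47 to 10.1), while SD day 5 stood at 1.03 times LD day 5 (interval 1.01 to 1.04). CATGAAGAAGTACGAGACACT had 4914 TPM in LD day 5 and 8369 in SD day 5, a ratio of 1.70 (interval 1.67 to 1.74). CATGAAGAAATACGAGACATT had 3263 and 6186 in the same libraries, a ratio of 1.90 (interval 1.85 to 1.94). In the day 2 pair, CATGAAGAAGTACGAGACACT stood at 0.642 and CATGAAGAAATACGAGACATT at 0.708 of the LD value. The 10 most abundant tags took 5.09% of the listed total in LD day 0 and 5.57% in SD day 2, against 8.31% in LD day 2, 8.33% in LD day 5 and 8.45% in SD day 5.

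Across the 8910 tags listed in every library, SD day 2 was most similar to LD day 0, with a Pearson r of log2 values of 0.906, against 0.859 with LD day 2. SD day 5 was most similar to LD day 5, with r = 0.943. The lowest correlation was between SD day 2 and SD day 5, at 0.749. These correlations are across tags, which are not independent replicates. The first principal component held 63.2% of the variance and placed SD day 2 at -0.62 and LD day 0 at -0.57, LD day 2 at 0.08, and LD day 5 at 0.51 and SD day 5 at 0.60.

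**Figure D1:**
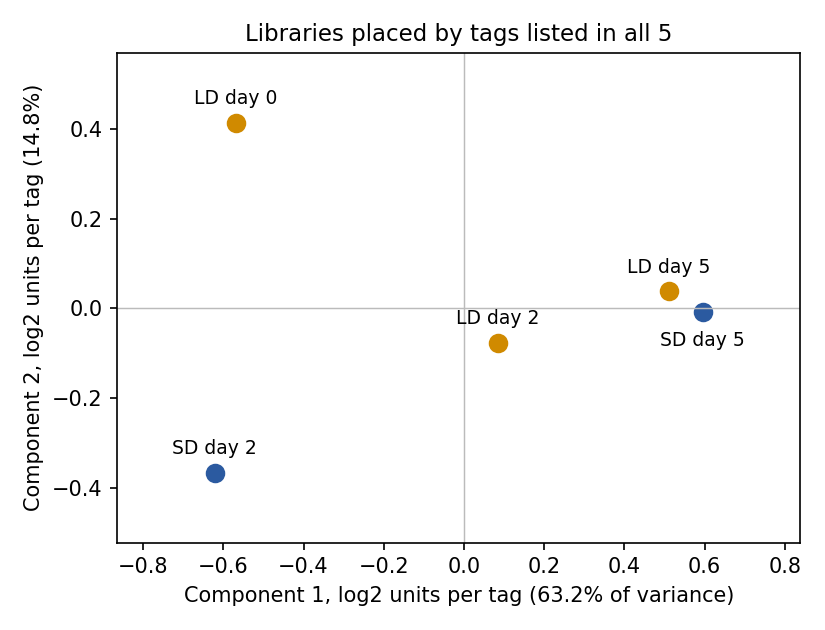
Position of the 5 libraries on the first and second principal components of log2(value + 1), in log2 units per tag, over the 8910 tags listed in all libraries; each point is 1 library, LD in orange and SD in blue. SD day 2 and LD day 0 lie at -0.62 and -0.57 on the first component, LD day 5 and SD day 5 at 0.51 and 0.60.

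The first photoperiod comparison asked which tags differed after 2 days in SD from plantlets kept in LD for the same time. Of 7108 tags compared, 531 were higher and 1441 lower in SD day 2 than in LD day 2, which is 27.7% of the tags. Differences of 4-fold or more on the log2 scale with the pseudocount were 32 higher and 570 lower. The largest on the higher side was CATGAAGTTTCGGTTAAAACG, at 34.8 TPM in SD day 2 and 0.85 in LD day 2, the latter resting on 3 tags, a 40.9-fold ratio (interval 13.7 to 202). It stood at 13.8 TPM in LD day 0, and its log2 ratio fell from 4.27 to 2.38 against the mean of the 3 LD libraries and to 2.77 with a pseudocount of 5 TPM. CATGTTTGGTTTCTTCGTTCA followed, at 292.8 against 20.9 TPM, 14.0-fold higher (interval 11.1 to 18.0). On the lower side, CATGTAAGTCCCCCATTTATT had 0.86 TPM in SD day 2, from 3 tags, against 55.0 in LD day 2, 64.0-fold lower (interval 21.7 to 314). CATGTTATATAGTTTCAATTT had 1.14 against 61.2 TPM, 53.7-fold lower (interval 20.7 to 199). CATGTAAGTCCCCCATTTATT stood at 8.46 TPM in LD day 0 and at 57.5 and 51.8 in LD day 5 and SD day 5. With the values rescaled to the listed tags the split was 1060 higher and 1629 lower, and it was 588 higher and 869 lower against LD day 0.

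After 5 days the photoperiods differed at fewer tags when each SD library was set against the LD library of its own day. Of 7194 tags compared, 197 were higher and 558 lower in SD day 5 than in LD day 5, or 10.5%. Against the mean of the 3 LD libraries the order of the days was not the same, with 1254 calls at day 2 and 1331 at day 5. That mean mixes days 0, 2 and 5, so these calls include change over time as well as photoperiod. They also rest on other sets of tags, 5789 at day 2 and 5886 at day 5. Between SD day 5 and LD day 5, differences of 4-fold or more numbered 22 higher and 43 lower. The balance of higher and lower calls at day 5 depended on the scaling: it was 296 higher and 407 lower with TMM, and 380 higher and 336 lower with median-of-ratios factors, so no direction is given for the set as a whole. These factors moved the median log2 ratio of the compared tags from -0.08 to 0.06 and 0.14. With a floor of 50 TPM the split was 80 higher and 119 lower. The largest single ratios lay far above those shifts. CATGCTTGGAGCTCTTGGCTG reached 3210 TPM in SD day 5 against 248.6 in LD day 5, 12.9-fold higher (interval 12.1 to 13.8). It had 434.9 in LD day 0 and 120.3 in SD day 2, and LD day 2 did not list it. Its log2 ratio moved from 3.685 to 3.81 with TMM and 3.88 with median-of-ratios factors, outside its counting interval. CATGGGCCTTTGCCACAAACT had 1256 against 97.6 TPM, 12.9-fold higher (interval 11.6 to 14.4), with 51.9 in LD day 2 and 30.2 in SD day 2. CATGAGGCCTGGAGACATTGT had 6.30 against 108.5 TPM, 17.2-fold lower (interval 11.2 to 27.8), and in the day 2 pair it also stood lower in SD, at 26.5 against 103.5. CATGGATTTCTAAATAAATTG had 21.5 against 290.1 TPM, 13.5-fold lower (interval 10.7 to 17.3), with 178.8 in SD day 2 and 131.7 in LD day 2; its log2 ratio moved from -3.70 to -2.87 against the mean of the 3 LD libraries.

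**Figure D2:**
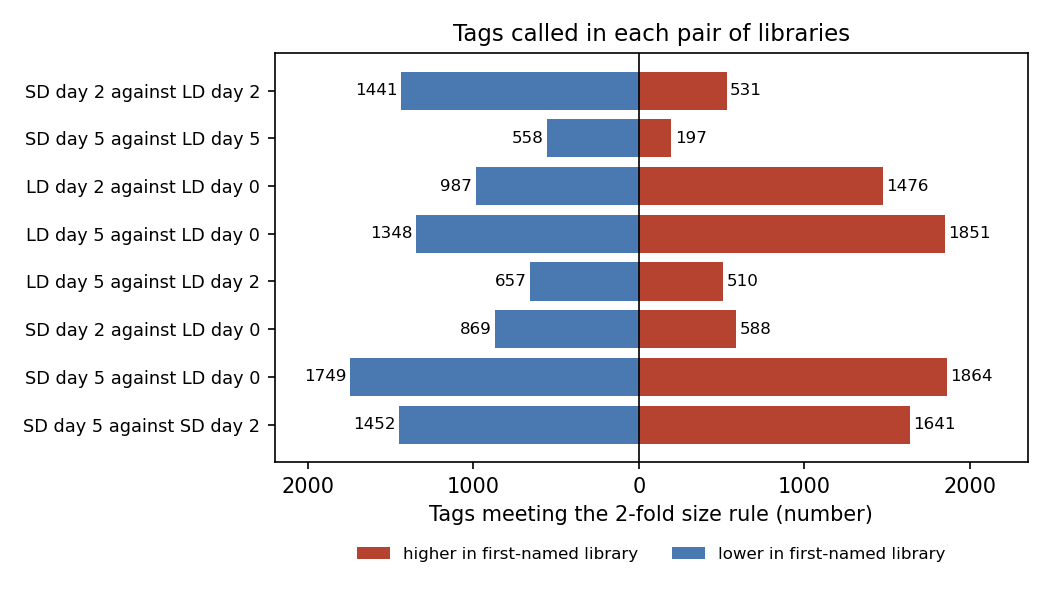
Number of tags called higher (red, right) or lower (blue, left) by at least 2-fold in the first-named library of each pair, 1 library per group and no test. SD against LD gave 531 higher and 1441 lower tags at day 2 and 197 higher and 558 lower at day 5, the latter split depending on the scaling.

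The agreement between days was examined in the 6381 tags listed in all 4 libraries of days 2 and 5 with at least 10 TPM in 1 of them. The log2 ratios of SD over LD on the 2 days were nearly uncorrelated across tags, with Pearson r = 0.06 and Spearman rho = 0.07. Tags higher in SD on both days numbered 34, against 10.2 expected of independent lists, and 7 of these differed 4-fold or more on both days. Tags lower on both days numbered 79, against 82.9 expected, and 5 of these differed 4-fold or more on both days. With TMM scaling the overlap was 48 higher tags against 16.1 expected and 64 lower against 58.4, and with median-of-ratios factors it was 62 against 25.5 and 42 against 44.7. The lower overlap was 44 against 34.8 with a pseudocount of 5 TPM and 23 against 19.0 with a floor of 50 TPM, so whether it lay above or below independent lists depended on the setting. A limma fit with day as a block found 0 tags at an adjusted p under 0.05, the lowest adjusted p being 0.63, while 264 of 6381 tags had an unadjusted p under 0.05, or 4.14%. That fit has 1 residual degree of freedom, and no other tool was run on it. A limma fit of the 3 LD against the 2 SD libraries without a day term gave 0 tags, with 65 of 6208 at an unadjusted p under 0.05. Change over time stays in the residual of that fit, so its 0 tags add no support.

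The tags farthest apart in 1 direction on both days were as follows. CATGTTTGGTTTCTTCGTTCA was at 355.4 TPM in LD day 0, 20.9 and 8.68 in LD days 2 and 5, and 292.8 and 95.9 in SD days 2 and 5, so that SD was 11.1-fold higher at day 5 (interval 7.68 to 16.4). CATGAAGTCATTGGGGCAAAA was at 43.1 in LD day 0, 1.69 and 2.98 in LD, and 34.8 and 32.4 in SD, a ratio of 20.6 at day 2 (interval 9.18 to 57.1) and 10.9 at day 5 (interval 5.84 to 22.3). CATGATAAAATTGTCGTTTTG was at 3.10 in LD day 0, 20.6 and 22.8 in LD, and 1.14 and 1.72 in SD, 18.1-fold lower at day 2 (interval 6.76 to 68.0) and 13.2-fold lower at day 5 (interval 5.84 to 37.1); with a pseudocount of 5 TPM its log2 ratios moved from -3.33 to -2.06 and from -3.13 to -2.05. CATGCAGTGTTTGTACCTGTT was at 4.79 in LD day 0, 111.1 and 160.8 in LD, and 8.27 and 28.4 in SD, 13.4-fold lower at day 2 (interval 9.21 to 20.3) and 5.67-fold lower at day 5 (interval 4.58 to 7.09). Set against the mean of the 3 LD libraries, the day 5 log2 ratio of CATGTTTGGTTTCTTCGTTCA turned from 3.32 to -0.42, and its day 2 ratio fell from 3.75 to 1.18, because LD day 0 held the highest value of that tag. CATGAAGTCATTGGGGCAAAA, also highest in LD day 0, fell from 3.73 to 1.08 at day 2 and from 3.07 to 0.98 at day 5, the latter below the size needed for a call. CATGCAGTGTTTGTACCTGTT moved from -2.46 to -1.67 at day 5. The size of these ratios therefore depends on which LD library is the control.

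**Figure D3:**
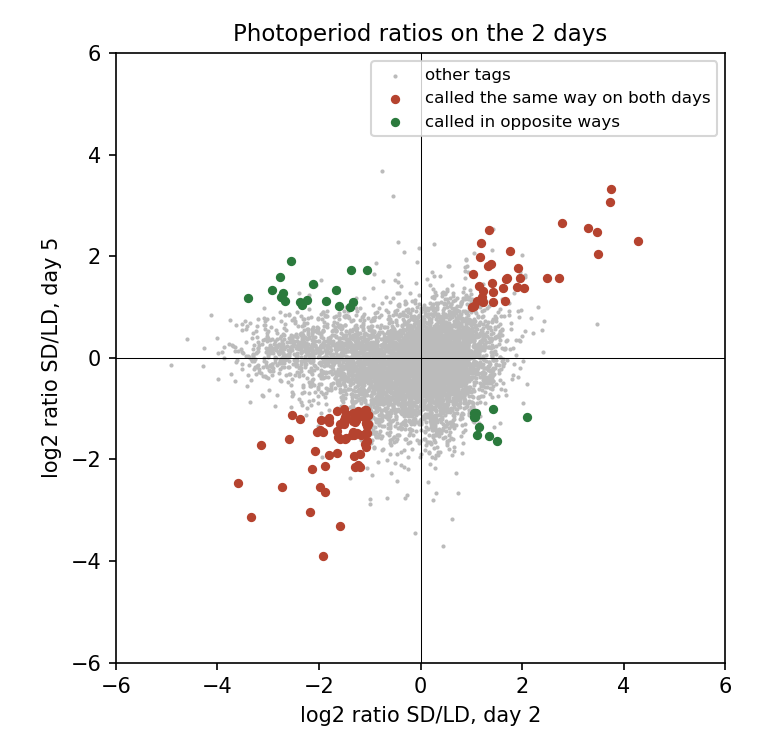
Log2 ratio of SD over LD at day 2 (x axis) and day 5 (y axis) for 6381 tags; red points were called the same way on both days and green points in opposite ways. The cloud shows little correlation (r = 0.06), with 34 tags higher on both days and 79 lower on both.

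**Figure D4:**
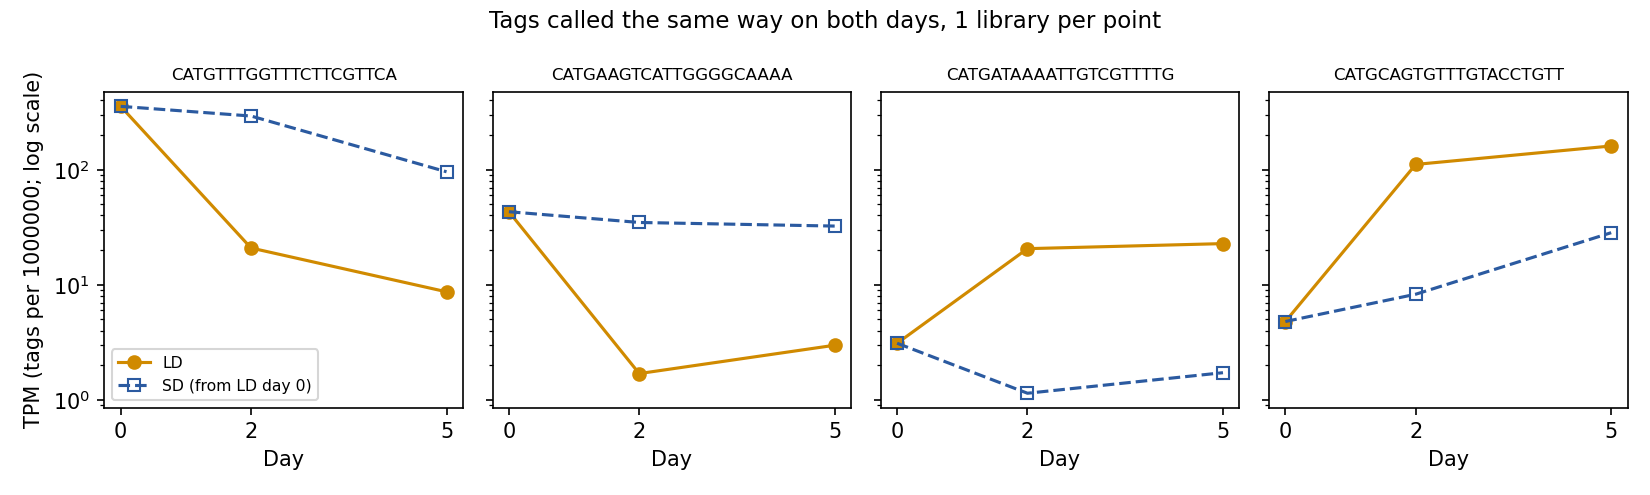
TPM (log axis) by day in LD (orange circles) and SD (blue squares, joined to LD day 0) for the 2 highest and 2 lowest tags called the same way on both days; each point is 1 library. In the first panel SD stays at 292.8 and 95.9 TPM while LD stands at 20.9 and 8.68.

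The LD libraries show how much tags differed with time where the photoperiod was not changed. LD day 2 had 1476 tags higher and 987 lower than LD day 0, and LD day 5 had 1851 higher and 1348 lower than LD day 0. Both balances depended on the scaling: median-of-ratios factors gave 1246 higher and 1189 lower for LD day 2 and 1553 higher and 1557 lower for LD day 5, and rescaling to the listed tags gave 1910 higher and 2029 lower for LD day 5. Between LD day 2 and LD day 5, 510 were higher and 657 lower at day 5, or 593 and 1056 after rescaling to the listed tags. By calls, fewer tags separated SD from LD at either day than separated LD day 2 or LD day 5 from LD day 0. This did not hold for LD day 5 against LD day 2, with 1167 calls. That was fewer than the 1972 of SD against LD at day 2, though more than the 755 at day 5. At 4-fold or more, the day 2 pair of SD and LD had 32 higher and 570 lower. In sum this was more than the 288 higher and 142 lower between LD day 2 and LD day 0, the other order. The sum stayed below that of the 553 higher and 472 lower between LD day 5 and LD day 0. By direction, the 32 higher were fewer than in both of these LD pairs, and the 570 lower were more. CATGCAATTACTGTTATGTTT was at 20.01 TPM in LD day 0 and 439.1 in LD day 2, 21.9-fold higher (interval 17.3 to 28.2), with 96.9 and 44.1 in SD days 2 and 5. CATGTTTGGATTTTTCGTTCA was at 544.8 in LD day 0 and 17.2 in LD day 2, 31.7-fold lower (interval 24.5 to 41.6). At 10.9 in LD day 5, it was 50.2-fold lower than at day 0 (interval 36.8 to 70.5). It was at 201.3 and 64.7 in SD days 2 and 5, above LD on the same days. CATGAAATCACATTTGACATT was at 19.4 in LD day 0 and 703.3 in LD day 5, 36.2-fold higher (interval 28.5 to 46.6). CATGTACTAGTTTGTTTGTTT was at 0.56 in LD day 0, from 2 tags, and at 131.0 in LD day 5, a ratio of 234 (interval 64.0 to 1924), with 59.3 in SD day 5. CATGGATATTGTAGTCAAACA was at 201.5 in LD day 0, 44.6 in LD day 2 and 0.54 in LD day 5, the last from 2 tags. It was at 109.2 in SD day 2, and SD day 5 did not list it. CATGTTTGCTTGAAAGGTTTA was at 2.26 in LD day 2 and 142.6 in LD day 5, 63.1-fold higher (interval 31.8 to 147), and at 6.56 and 126.0 in SD days 2 and 5.

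Set against the same LD day 0 library, SD day 2 had 588 tags higher and 869 lower, and SD day 5 had 1864 higher and 1749 lower. The split of SD day 5 turned to 1872 higher and 2552 lower after rescaling to the listed tags, with the median log2 ratio moved from 0.02 to -0.21, and was 2339 higher and 2378 lower with no floor. SD day 5 had 1641 tags higher and 1452 lower than SD day 2; rescaled to the listed tags, that split was 1681 higher and 2383 lower, with the median log2 ratio moved from -0.03 to -0.31. In SD day 2, CATGCAAGCTAAATATCTCGG was at 25.9 TPM against 1.41 in LD day 0, 18.4-fold higher (interval 7.61 to 58.1). It was also above LD day 0 without the transfer, at 20.59 in LD day 2 and 49.35 in LD day 5, with 17.75 in SD day 5. CATGCTGCAGTAGAGCGACTT was at 3.99 in SD day 2 against 63.1 in LD day 0, 15.8-fold lower (interval 9.23 to 29.4), and at 46.8 or more in the other 3 libraries. CATGAAATCACATTTGACATT was at 1069 TPM in SD day 5, 54.9-fold higher than in LD day 0 (interval 43.3 to 70.8), with 703.3 in LD day 5. SD day 2 did not list it. CATGCTTGTCTGTAAATTTGA was at 381.6 in LD day 0 and 8.59 in SD day 5, 44.4-fold lower (interval 31.0 to 66.1). It was also below day 0 in LD, at 89.4 in LD day 2 and 45.0 in LD day 5. Between the SD days, CATGACATAAAAGAAGCTGTT was at 3.71 in SD day 2 and 353.1 in SD day 5, 95.2-fold higher (interval 55.5 to 179). It also rose in LD, from 9.86 at day 0 to 81.5 at day 2 and 196.3 at day 5. CATGCAAAGGAACAAATTTGA was at 322.8 in SD day 2 and 9.74 in SD day 5, 33.1-fold lower (interval 23.6 to 48.1), with 74.0 in LD day 5.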

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

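The tests of tags listed in only some libraries were chosen after the result was seen.

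In 28 of the 6381 tags listed in the 4 libraries of days 2 and 5, SD and LD were called in opposite directions on the 2 days, 10 of them higher at day 2 and lower at day 5, and 18 the other way. The number expected of independent lists was 30.0 and 28.1. The difference between days was not tested, as each value is 1 library. The 2 tags farthest apart were CATGTAATTCAAGTTGAGGGT, with a log2 ratio of -3.40 at day 2 and 1.19 at day 5, and CATGTTTAATTAGATGTAATT, with -2.55 and 1.90; the -2.55 became -1.43 with a pseudocount of 5 TPM.

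A signal lay outside the comparisons in 2850 tags that a single library listed at 10 TPM or more. Abundant tags were among those unlisted elsewhere: of the 2201 tags above 50 TPM in SD day 5, LD day 5 did not list 19.6%. A value of 2 tags was enough to be listed. That share is the pattern itself, so by itself it does not decide whether loss of detection was the cause. All libraries kept their shared tags in 1 order, and where exactly 1 unlisted tag stood between the same shared tags in both libraries, the values of the 2 different tags correlated at r = 0.946 over 1615 such rows of SD day 5 and LD day 5, against 0.947 for shared tags and 0.03 for neighbouring rows. Where LD day 5 listed nothing in the place of 1 tag of SD day 5, the 335 tags had a median of 0.57 TPM, and 0 reached 10 TPM. The other way, the median of 652 tags was 0.81 TPM, and 1 reached 10 TPM. For these rows of this pair, that argues against loss of detection of abundant tags. In SD day 5 against SD day 2, 26 of 536 such tags reached 10 TPM. A candidate explanation is that a row stands for 1 transcript unit, listed under 1 tag that can differ between libraries. No biological explanation was tested.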

How the results depend on the processing

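The counting interval removed no call, so the rule without it gave the same counts and is not included among the alternatives below. TMM, median-of-ratios scaling, a pseudocount of 0.1, and, added after seeing the data, rows under different tags, rescaling to the listed tags and tags listed in all 5 libraries kept each total of calls within 1.5 times, though not always its higher and lower parts. In 9 alternatives the share of calls on the higher side moved by over 10 points. In all, 75 of 104 alternative values of counts and correlations stayed within that range or the interval of the correlation, and 29 did not, as follows. With a floor of 50 TPM the calls were 618 (SD against LD, day 2), 199 (SD against LD, day 5), 815 (LD day 2 against day 0), 1054 (LD day 5 against day 0), 335 (LD day 5 against day 2), 440 (SD day 2 against LD day 0), 1215 (SD day 5 against LD day 0), 1042 (SD day 5 against SD day 2) and 35 on both days in 1 direction, since fewer tags were tested. With unlisted tags set to 0, added after seeing the data, they were 5512, 3793, 6024, 6981, 4710, 4485, 7292, 6787 and 690 in the same order. Under that setting every tag at 10 TPM or more in 1 library and unlisted in the other is called by construction, so these counts could only rise. With no floor they were 1265 (SD against LD, day 5), 1754 (LD day 5 against day 2), 2211 (SD day 2 against LD day 0) and 172 on both days, and with a pseudocount of 5 they were 411, 749, 946 and 70 for the same results. Against the mean of the 3 LD libraries SD day 2 gave 1254 and SD day 5 1331 calls, so the order of the days turned. Against LD day 0 SD day 5 gave 3613. Both of these controls add change over time to the photoperiod difference, so they do not test the same-day order alone. Of the named tags' SD/LD ratios, 69 of 93 alternative values lay within the counting interval and 1 reversed: CATGTTTGGTTTCTTCGTTCA at day 5 was -0.42 against the mean LD library, because LD day 0 was high. Apart from the shifts with a floor of 50 TPM and with unlisted tags set to 0, the cause of the other shifts was not tested. Gene list alternatives were not run, as tags have no gene names. No paired analysis was possible because the labels give no replicate numbers, other than pairing SD and LD by day in the limma fit, which had 1 residual degree of freedom and gave 0 tags. Values near 10 TPM rest on few tags, which limits ratios close to 2-fold, and differences of 1 library from another cannot be told from differences between plantlets or preparations.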

Other observations

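The comparison of tags shared by both days with LD day 0 was chosen after the results had been seen. So were the test of slower progress in SD day 2 and the comparisons of depth and listed share. The checks on GC content and abundant tags were set before their results.

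Tags that separated the photoperiods on both days were compared with LD day 0. Of the 34 tags higher in SD on both days, 33 were listed in LD day 0, and 20 of these were called lower in both LD day 2 and LD day 5 than in LD day 0. In 8 of those 20, neither SD library was called different from day 0. Both SD libraries were called higher than day 0 in 3 of the 33, and in 2 of those 3 neither LD library was called. Of the 79 tags lower in SD on both days, 72 were listed in LD day 0, 33 of these were called higher in both later LD libraries, and in 20 of those 33 neither SD library was called. Both SD libraries were called lower than day 0 in 10 of the 72, and in 8 of those 10 neither LD library was called. Choosing tags by SD against LD favours tags in which LD moved or SD moved, so the 2 kinds were set side by side, and the shared day 0 library enters all of these calls.

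SD day 2 lay closer to LD day 0 than to LD day 2, and the day 2 pair gave 1972 calls against 755 at day 5. Against the mean LD library, which mixes days, the counts were 1254 and 1331. The excess of the same-day calls at day 2 is not accounted for by GC content of the tags, abundant tags or depth as the whole cause: the ratio of day 2 to day 5 calls was 2.75 with the GC trend removed and 2.78 without the 100 most abundant tags, and library totals differed by 1.01 times in the day 2 pair and 1.06 times in the day 5 pair, which had fewer calls. That SD day 2 plantlets had moved less along the change that LD plantlets made over time stays open: across tags, the SD/LD log2 ratio at day 2 correlated at r = -0.62 with LD day 5/LD day 0, but the correlations between libraries, seen before, already imply about -0.56, so this decides nothing. A different harvest hour, culture or library batch, or exchanged labels of the day 2 libraries, cannot be told apart from it, as 0 labels give such a record and each group is 1 library.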
